A study of Homo sapiens with 30 samples.

How the data were processed

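Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on BJ cells, an established line of human skin fibroblasts, 72 h after they received 1 of 4 vectors. These were an empty control vector, wild-type p63, wild-type p63 together with KLF4, and p63 carrying I537T, a change in its SAM domain, together with KLF4. H3K27ac, a histone mark of active enhancers and promoters, and the Flag tag of p63 were precipitated with all 4 vectors. KLF4 was precipitated with the control vector and both KLF4 vectors. Each of the 11 combinations of vector and antibody had 2 libraries, described by the submitters as biological duplicates. The vector field of the mutant samples carries changing KLF numbers, so groups were taken from the sample titles. Of the 30 samples, 22 had a peak list; the 8 input samples were not analysed here.

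The authors deposited 1 peak list per library, so replicates were called separately. Reads were aligned with Bowtie2 and peaks called with MACS2 on GRCh37/hg19, per the submitters' processing notes; tool versions, and whether an input served as the control of the peak call, are not given in the sources used here. For each peak the deposited lists hold a position, a summit offset, a fold enrichment over the local background (a ratio), a −log10 p-value and −log10 q-value, and a score that is the whole part of 10 times the −log10 q-value. Every deposited q-value was at most 0.01. These values are the authors' own and served only to rank or describe peaks within a list. Read depth is unknown, and no read counts were used. The number of peaks in a list moves with depth and with the quality of the precipitation, and it differed between replicates of most groups. Binding and acetylation are therefore measured as presence of a peak, not as signal, and a peak missing from a short list does not show that the site was unoccupied.

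Peaks on chromosomes 1 to 22 and X were kept. Intervals overlapped when they shared at least 1 bp. A p63 site or KLF4 site is a merged interval with a peak in both replicates of a vector and no peak of that antibody in either control-vector library. H3K27ac sites are the merged union of the peaks of all 8 H3K27ac libraries. A site was gained when both libraries of a vector and neither control library had a peak, and lost in the reverse case. The replicate error of these counts was taken from mixed splits of the same 4 libraries, which set 1 control and 1 vector library against the other 2. To set libraries side by side at equal list length, the most significant peaks of each were used, 40991 for H3K27ac, 33350 for Flag and 24907 for KLF4, each being the length of the shortest list concerned. Background overlap was measured after moving the sites by 20000 bp in both directions. Sites are not replicates, so no p-value was computed across sites.

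Shares of sites with H3K27ac were compared between libraries with exact permutation tests of the difference in means. Grouping of libraries by vector was tested over all pairings of the libraries with the Jaccard index, the bases shared by both lists over the bases covered by either. A two-sided test of 2 against 2 libraries cannot give a p below 0.333. Overlap of gained sites between vectors was set beside the value for independent lists and beside 100 simulated pairs of unchanged groups with the same control libraries, in which each site was present at its mean rate over the 8 libraries. That rate contains the effects of the vectors.

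Single regions were named by a fixed rule: the 5 p63 sites of each vector with the highest mean rank of peak significance. Regions gained with all 3 p63 vectors were listed by their number of p63 sites, a rule chosen after the data were seen. The only gene table at hand lies on another genome build, so no gene was assigned to a peak, and the planned gene lists, motif shares and check for vector DNA were not run. Groups, site definitions, the tests of H3K27ac shares and of grouping, and most alternatives were fixed before the data were examined. Chosen afterwards were the comparison of p63 sites with and without a KLF4 site, the new acetylation at p63 sites, the classes of sites bound with only 1 vector, the acetylation of p63 sites in control cells, summit distances, the direct comparison of p63 vectors, fibroblast sites of control replicate 2, and the classing of libraries by peak names. The latter rests on the prefix of the peak names in a list, which is BJ-, BJChIP or absent; it crosses the replicate numbers and serves as a stand-in for a processing batch.

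Alternatives were stricter peak sets, an overlap of at least 50% of the shorter interval, no removal of control-vector peaks, equal list lengths, directly counted peaks, blocks for replicate number or peak-name class, and leaving out each replicate number in vector and control alike. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The interval functions were checked against bedtools 2.31.1 on deposited lists. The calling of gained and lost sites was tested on simulated data, in which a copy of the control libraries lost 10% of its peaks at random, 200 sites were planted and 200 removed. All 200 planted and all 200 removed sites were recovered among 99530 union sites; 0 other sites were called gained and 207 others lost. This checks that the calls follow the definition, which planted sites meet by construction, and not their error rate.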

Results

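Flag-p63, KLF4 and H3K27ac were mapped in BJ fibroblasts carrying an empty control vector, wild-type p63, wild-type p63 plus KLF4, or mutant p63 (I537T, SAM domain) plus KLF4. p63 is a transcription factor of stratified epithelia, KLF4 is a zinc-finger transcription factor of differentiating epidermis, and their joint expression addresses conversion of fibroblasts towards keratinocytes. Each vector and antibody had 2 libraries. The H3K27ac lists held 98854 and 45415 peaks with the control vector, 79019 and 151492 with wild-type p63, 111891 and 40991 with wild-type p63 plus KLF4, and 100064 and 64688 with mutant p63 plus KLF4. Flag lists held 29710 and 948 peaks with the empty control vector, against 33350 to 151328 with p63 vectors. KLF4 lists held 2426 and 1613 peaks with the control vector, 117093 and 24907 with wild-type p63 plus KLF4, and 44271 and 50898 with the mutant. Read depth is unknown.

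Peak number differed between replicates of most vectors, most for Flag in control cells, and the lists also fell into classes by the prefix of their peak names. The control vector, wild-type p63 plus KLF4 and mutant libraries of replicate 1 carried the prefix BJ- for Flag and H3K27ac. Their replicate 2 libraries and wild-type p63 replicate 1 carried no prefix, and wild-type p63 replicate 2 carried BJChIP. For H3K27ac the list without prefix was the shorter list of each vector, so class cannot be told apart from list length there. Values within a class are given below where a control library of that class exists.

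The first question was where p63 binds in fibroblasts. Wild-type p63 occupied 41658 sites in both replicates and in neither control library, wild-type p63 plus KLF4 occupied 47892 and the mutant 25966. The median site was 428, 414 and 363 bp wide. At equal list length, 67.2% to 77.4% of the p63 peaks of a library recurred in the other replicate of its vector. The control Flag peaks touched few of these sites: 1229, 1834 and 2119 sites were removed for the 3 vectors. The number of sites followed the shorter list: without replicate 2 of vector and control, replicate 1 gave 148254, 119518 and 58386 sites.

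The strongest p63 sites were shared by all p63 vectors. All 15 sites named by significance, 5 per vector, were p63 sites of each vector. They fell into 13 separate regions, of which 9 had no H3K27ac peak in either control library. With wild-type p63 the leading site lay on chromosome 7 from 102244689 to 102245601 (GRCh37/hg19), with fold enrichments of 124.1 and 58.4 in the replicates, and was acetylated in all 8 libraries. With wild-type p63 plus KLF4 it lay on chromosome 4 from 513035 to 514479, with fold enrichments of 191.7 and 73.7. That site lacked H3K27ac in the controls and had it in 1 of 2 libraries of each wild-type vector. With the mutant it lay on chromosome 4 from 7707523 to 7708639, with fold enrichments of 129.9 and 127.5, and was acetylated in 1 control library and all 6 p63 libraries. Fold enrichments are the authors' peak values and are not comparable between lists.

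The second question was what KLF4 changes in p63 binding. Of the p63 sites of wild-type p63 plus KLF4, 44.2% were also sites of wild-type p63 alone, against 2.91% for moved sites. A peak in at least 1 library of wild-type p63 was found at 74.8%, a measure for which no moved share was computed. In the other direction 50.7% and 73.6% of wild-type p63 sites were found with KLF4. Sites without any Flag peak in the other p63 vectors numbered 10479 for wild-type p63 and 5533 for wild-type p63 plus KLF4. Replicates of a vector resembled each other more than libraries of different p63 vectors did. Their mean Jaccard index was 0.412 against 0.25 for the other pairs; the real pairing ranked first of 15, p = 0.0667 in the one-sided exact test, the smallest this design allows. With all deposited peaks the difference fell from 0.162 to 0.05, with an exact p of 0.2. Pairs of different vectors within a peak-name class had a mean index of 0.262, below that of replicates, which were all of different classes.

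The third question was what the SAM-domain mutation changes. Nearly all mutant p63 sites overlapped peaks of wild-type p63 plus KLF4: 98.1% had a peak in at least 1 of its libraries. No share of moved sites was computed for this measure. Of the mutant sites, 76.4% were sites of wild-type p63 plus KLF4, against 4.09% for moved sites. Only 235 mutant sites had no peak with either wild-type vector. The reverse share was lower, as 41.1% of wild-type p63 plus KLF4 sites were mutant sites and 64.0% had a mutant peak. Flag lists held 127853 and 54044 peaks with wild-type p63 plus KLF4 and 72033 and 33350 with the mutant. The unequal shares and the count of 235 are therefore not independent of list length and do not show that mutant binding is a subset. With the 25966 strongest sites of each vector the shares were 56.3% and 55.7%, which equal numbers make nearly equal by construction.

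Mutant p63 sites were more often acetylated in cells with the control vector than wild-type sites were. H3K27ac covered 44.2% and 21.1% of mutant sites in the control libraries, against 28.9% and 12.4% of wild-type p63 plus KLF4 sites, with 11.04% and 3.71% for moved mutant sites. Wild-type p63 plus KLF4 sites shared with the mutant reached 44.7% and 21.3%, and those not shared 17.8% and 6.18%. At equal list length the mean over the control libraries was 30.2% ± 1.30 (SD, n = 2) in mutant Flag libraries and 21.4% ± 2.21 (SD, n = 4) in wild-type Flag libraries. Both mutant libraries lay above all 4 wild-type ones; the two-sided exact permutation p was 0.0667, the smallest of 15 splits. Within peak-name classes the mutant exceeded wild-type p63 plus KLF4 as well, at 31.2% against 19.5% with the prefix BJ- and 29.3% against 19.8% without prefix. This comparison was chosen after the data were seen.

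**Figure D1:**
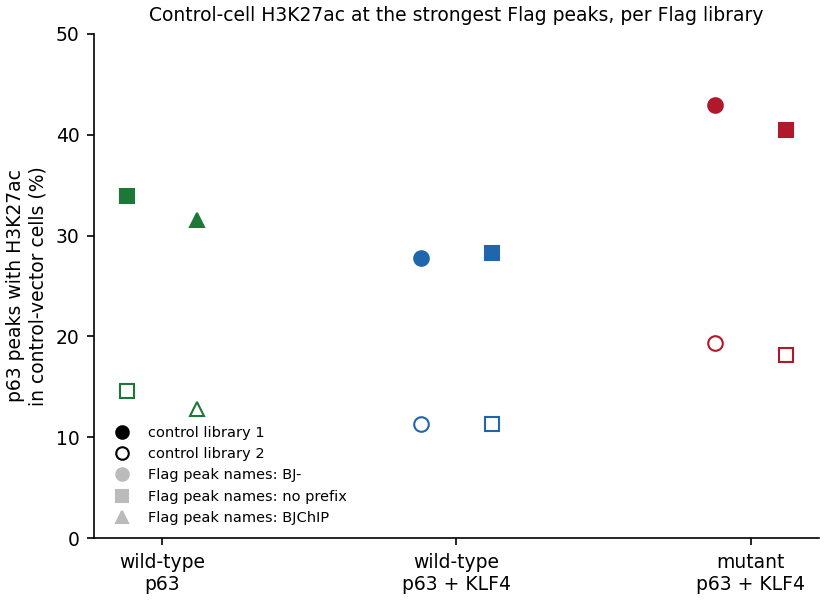
Share of the strongest Flag peaks of each library (up to 33350, control Flag peaks removed) that overlap H3K27ac in control-vector cells, on the vertical axis in percent, by p63 vector. Filled and open symbols stand for the 2 control libraries and symbol shapes for the peak-name class; the mutant libraries reach 43.0% and 40.5% in control library 1, against 27.8% to 33.9% for the wild-type libraries.

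The fourth question was how KLF4 and p63 share sites. KLF4 occupied 21275 sites with wild-type p63 and 31098 with mutant p63; 64.4% of the former were sites of the latter and 45.4% the reverse. From 1 replicate number of vector and control, replicate 1 gave 115076 sites for the wild type and replicate 2 gave 50177 for the mutant. Of p63 sites, 25.6% held a KLF4 site with the wild type and 39.7% with the mutant, against 2.73% and 3.19% for moved sites. From replicate 1 of vector and control alone, 58.3% and 37.4% of p63 sites held a KLF4 site, and from replicate 2 alone 25.3% and 46.3%. Of KLF4 sites, 56.9% and 33.1% held a p63 site. The vectors were not separable at equal list length, where 28.4% to 33.1% of wild-type and 29.9% to 33.0% of mutant p63 peaks met a KLF4 peak. In p63 peaks of replicate 1 bound by both factors the median distance between summits was 51 bp with wild-type and 56 bp with mutant p63. Among wild-type p63 plus KLF4 sites, KLF4 was found at 35.9% of the 11041 shared by all p63 vectors and at 13.9% of the 5533 bound only with this vector. It was found at 31.9% of the 12077 sites without a Flag peak of wild-type p63 alone and at 23.4% of the 35815 sites with one.

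The fifth question was whether p63 sites become acetylated. At equal list length H3K27ac covered 19.9% and 12.2% of all p63 sites in the control libraries, 22.99% and 30.2% with wild-type p63, 32.3% and 16.1% with wild-type p63 plus KLF4, and 24.1% and 17.5% with the mutant. Moved sites reached 7.08% and 3.22% in the controls and 4.6% and 7.88% with wild-type p63. They reached 8.69% and 3.24% with wild-type p63 plus KLF4 and 7.69% and 4.4% with the mutant. Equal list length thus did not equalise background overlap, and the shares, differences and p-values here are not corrected for it. The 6 p63 libraries averaged 23.9% ± 6.55 (SD, n = 6) and the controls 16.0% ± 5.43 (SD, n = 2). The difference of 7.84 percentage points did not pass 0.05, with p = 0.107 in the one-sided exact permutation test (3 of 28 splits). It was 14.1 points with all deposited peaks, 4.53 with 50% of the list length and 4.92 with an overlap of at least 50%, with exact p of 0.143, 0.107 and 0.214. Within peak-name classes, each of the 5 p63 libraries with a control of its class lay above that control, by 3.86 to 12.4 points, and with the class as a block, chosen after the data were seen, the exact p was 0.0833, the smallest that block allows, with the real split the most extreme.

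Acetylation was next counted at p63 sites that lacked it in control cells. Of p63 sites without H3K27ac in either control, 21.2% of 27783 had it in both libraries of wild-type p63, 5.91% of 34022 with wild-type p63 plus KLF4, and 8.98% of 14454 with the mutant; moved sites reached 1.29%, 0.54% and 0.75%. Sites chosen in this way can only gain, and p63 sites exceed moved sites in mixed splits too, so these shares are no test of a vector's effect. Equal list lengths gave 13.6%, 7.44% and 8.18%, in the same order. The order held in replicate 2 alone, with 53.6%, 6.03% and 9.71% from all peaks, but not in replicate 1 alone, with 21.3%, 42.8% and 28.6%. These shares were computed after the data were seen.

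The presence of KLF4 at p63 sites was compared next. In cells with a KLF4 vector, p63 sites that held a KLF4 site were acetylated more often than p63 sites without KLF4, and by a wider margin than in cells without it. For the sites of wild-type p63 plus KLF4 the margin was 25.02 ± 6.63 percentage points (SD, n = 4) in the KLF4-vector libraries and 10 ± 0.62 (SD, n = 4) in the others, a difference of 15.02 points. For the sites of the mutant it was 25.3 ± 3.16 (SD, n = 4) and 11.6 ± 1.01 (SD, n = 4), a difference of 13.8 points. In both cases all 4 KLF4-vector libraries lay above all 4 others, two-sided exact permutation p = 0.0286, the smallest of 70 splits. The contrast was chosen after the data were seen. Its p63 and KLF4 sites were called in cells with the KLF4 vectors, so the margins are not independent of the choice of sites. With the peak-name class or the replicate number as a block the exact p was 0.0556, again the smallest possible, so the result did not pass 0.05 with either block.

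The same pattern appeared within peak-name classes. At wild-type p63 plus KLF4 sites with a KLF4 site, H3K27ac lay above the class control by 36.2 and 17.1 points with wild-type p63 plus KLF4 and by 15.7 and 14.2 points with the mutant. At its sites without KLF4 the same libraries exceeded the control by 12.3, 2.94, 2.98 and 4.27 points. For wild-type p63 alone only replicate 1 had a control of its class. It exceeded that control by 10.9 points at the former sites and 10.2 points at the latter.

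**Figure D2:**
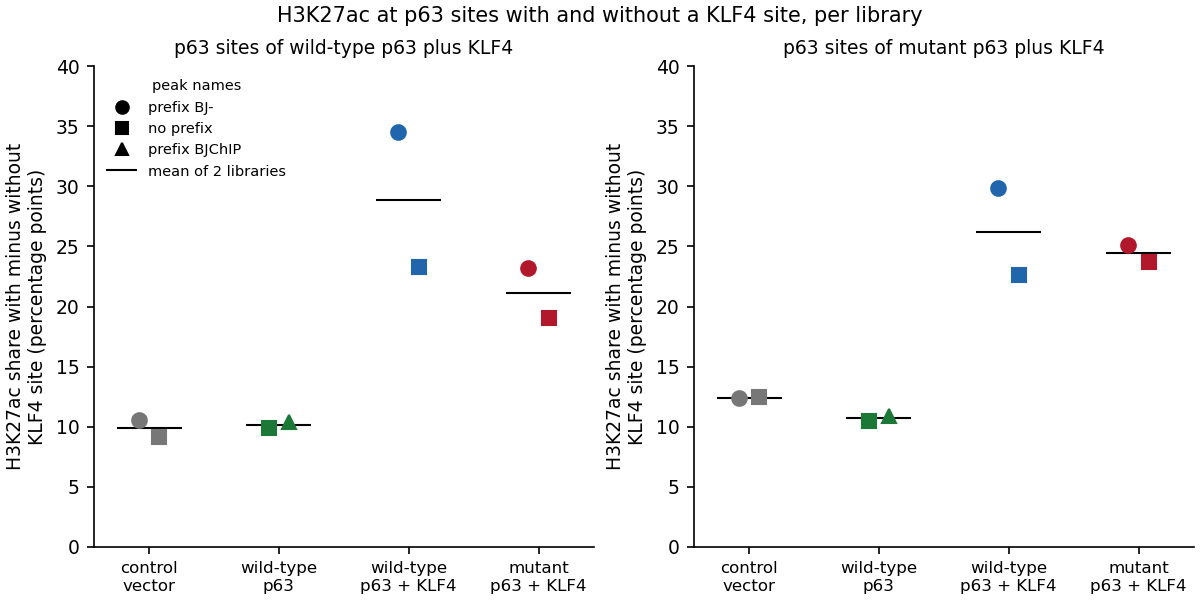
H3K27ac share of p63 sites with a KLF4 site minus that of p63 sites without one, in percentage points at equal list length, for each H3K27ac library (points; shape, peak-name class) with the mean per vector (line). For the sites of wild-type p63 plus KLF4 the 4 KLF4-vector libraries lie between 19.1 and 34.5 points, and the 4 others between 9.17 and 10.5.

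KLF4 sites without any p63 peak, 6128 in all, gave no difference past 0.05. H3K27ac covered 31.6% ± 9.66 (SD, n = 4) of them with KLF4 vectors and 23.3% ± 4.87 (SD, n = 4) without, two-sided exact permutation p = 0.171. The difference of 8.33 points was 1.66 without replicate 1 and 15.01 without replicate 2 of all vectors. Both mutant libraries lay above their class control, by 11.2 and 11.4 points, while wild-type p63 plus KLF4 gave 9.27 points in replicate 1 and −1.13 in replicate 2.

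Sites bound only with wild-type p63 were acetylated more often in both of its libraries than in any other, while for sites bound only with wild-type p63 plus KLF4 this held for 1 of its 2 libraries. At the 10479 sites bound only with wild-type p63, H3K27ac at equal list length reached 18.6% and 26.6% with wild-type p63, against 12.2% and 6.79% in the controls, 8.09% and 4.03% with wild-type p63 plus KLF4, and 9.32% and 6.16% with the mutant. At the 5533 sites bound only with wild-type p63 plus KLF4, it reached 15.02% and 3.09% with that vector, against 4.14% and 1.17% in the controls, 1.66% and 4.39% with wild-type p63, and 5.89% and 2.48% with the mutant. Moved sites of this second class reached 7.58% and 2.64% with wild-type p63 plus KLF4, 5.62% and 2.30% in the controls, 3.61% and 6.57% with wild-type p63, and 6.38% and 3.53% with the mutant, so only the libraries of wild-type p63 plus KLF4 lay above their background. Moved sites of the first class reached 3.43% and 6.25% with wild-type p63, 5.85% and 2.60% in the controls, 5.46% and 1.99% with wild-type p63 plus KLF4, and 5.51% and 3.07% with the mutant. Over all 41658 wild-type p63 sites, the 4 KLF4-vector libraries lay above the control of their peak-name class, by 1.83 to 7.58 points. The classes were formed after the data were seen, by a Flag peak in both libraries of a vector and none with the other p63 vectors, so the acetylation shares are not independent of that choice, and these differences were not tested.

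**Figure D3:**
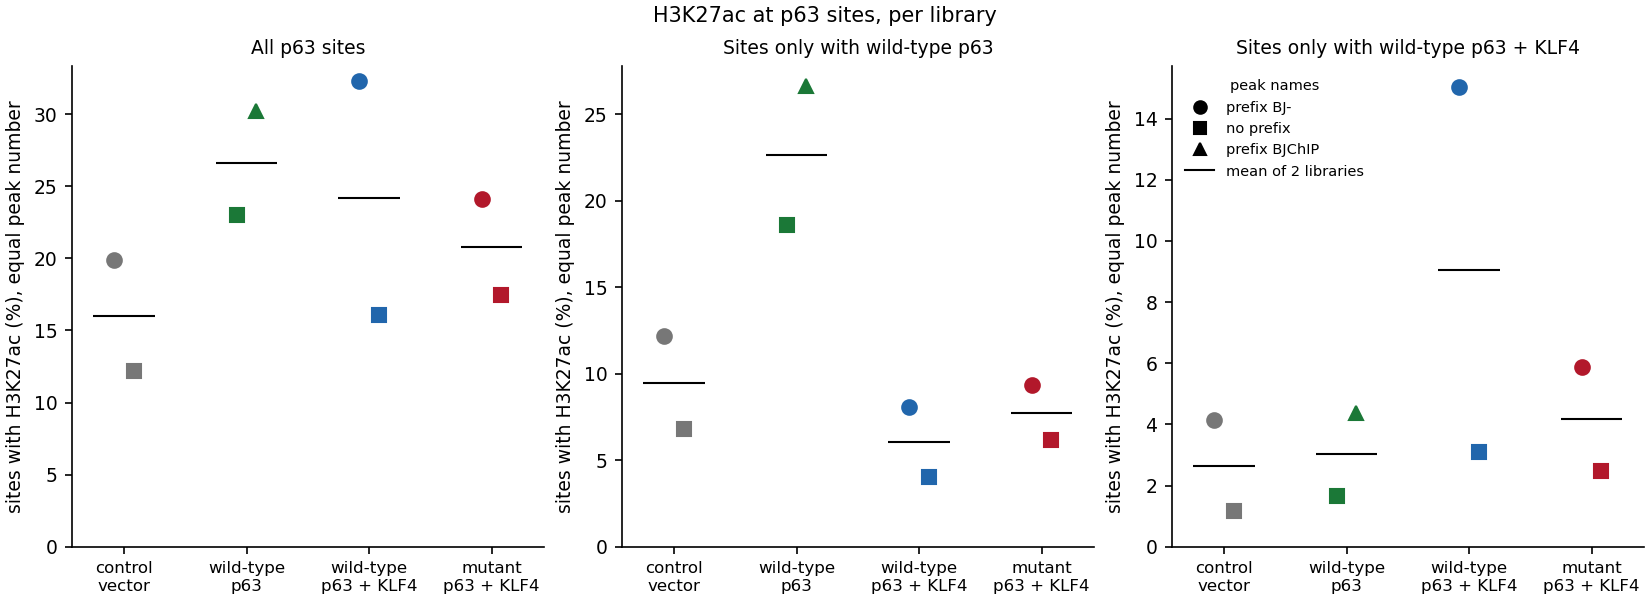
Share of p63 sites with H3K27ac in each library at equal list length (vertical axis, percent), for all p63 sites, for those bound only with wild-type p63 and for those bound only with wild-type p63 plus KLF4. Points are libraries, shapes the peak-name class and lines the mean of 2 libraries; in the middle panel wild-type p63 lies at 18.6% and 26.6%, above all other libraries.

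H3K27ac was then compared across the genome. The union held 190885 sites, and 16353 had a peak in all 8 libraries. With all deposited peaks, 12160 sites were gained and 710 lost with wild-type p63, 3022 gained and 1816 lost with wild-type p63 plus KLF4, and 3759 gained and 556 lost with the mutant. Mixed splits of the same libraries gave up to 18388, 18720 and 17708 sites, so none of these counts exceeded the largest mixed split. Those largest splits hold sites of the longer list of control and vector, so they also follow list length. The other mixed counts reached at most 219, 312 and 444. At equal list length gained sites numbered 6569, 4344 and 3253 and lost sites 3496, 4698 and 2083. The largest mixed splits were then 1673, 2430 and 2638; all these gained and lost counts were above them except lost sites with the mutant. Gained sites outnumbered lost sites with each vector when all peaks of both replicates were used, but with wild-type p63 plus KLF4 not at equal list length. Leaving out a replicate number in vector and control together left the gained sites of wild-type p63 at 12886 without both replicates 2 and gave 103110 without both replicates 1. For wild-type p63 plus KLF4 it gave 45412 and 7822 gained sites, and for the mutant 22653 and 16325, in the same order. Lost sites numbered 43423 and 1444 with wild-type p63, 34438 and 11423 with wild-type p63 plus KLF4, and 27161 and 3452 with the mutant, again in this order. Lost sites thus outnumbered gained ones without replicates 2 for wild-type p63 and the mutant, and without replicates 1 for wild-type p63 plus KLF4.

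Sites gained in both libraries of a vector held a p63 site more often than the comparison sets did. A p63 site lay in 49.6% of sites gained with wild-type p63, in 68.0% with wild-type p63 plus KLF4 and in 34.2% with the mutant. The largest mixed splits gave 8.96%, 20.4% and 9.87%, sites acetylated in both controls 26.8%, 27.2% and 23.8%, and lost sites 3.52%, 2.81% and 1.44%. The gained sites themselves, when moved, gave 4.44%, 11.1% and 5.25%. With the same number of p63 sites per vector, the shares were 36.4%, 47.7% and 34.2%. Gained sites called from the H3K27ac libraries of replicate 1 alone held a p63 site in 47.3%, 32.2% and 17.6% of cases, and those of replicate 2 alone in 22.6%, 53.8% and 25.9%. The shares of wild-type p63 in replicate 2 and of the mutant in replicate 1 lay below those of sites acetylated in both controls.

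KLF4 sites lay in 52.4% of the sites gained with wild-type p63 plus KLF4 and in 56.1% of those gained with the mutant. Both factors lay in 43.1% and 25.7% of the gained sites, p63 without KLF4 in 24.9% and 8.49%, KLF4 without p63 in 9.30% and 30.4%, and neither in 22.7% and 35.4%. Lost sites had neither factor in 96.9% and 98.0% of cases. In the largest mixed splits this share was 75.2% and 84.7%, and in mixed sites of replicate 2 alone 99.7% and 98.6%. Sites acetylated in both controls had neither factor in 62.6% and 53.9% of cases. They held KLF4 without p63 in 10.2% and 22.2%, so with the wild type this class was no more frequent among gained sites. Sites are not replicates, and these shares carry no p-value.

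**Figure D4:**
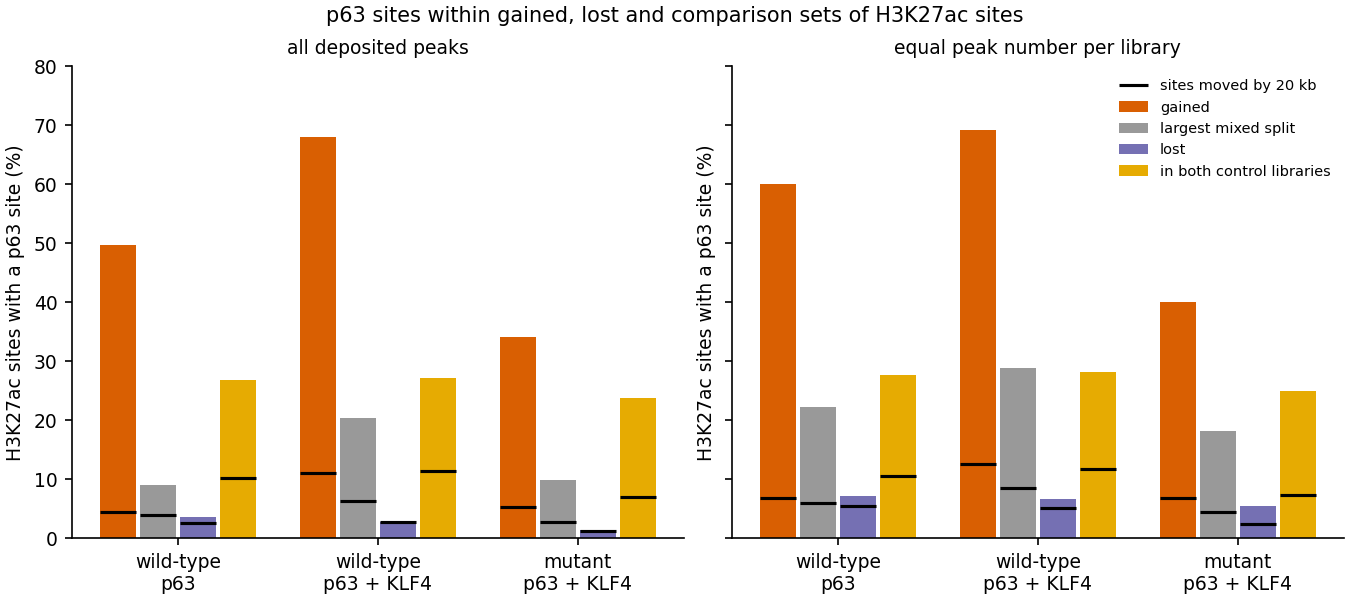
Percentage of H3K27ac sites that hold a p63 site of the same vector (bars, from 0), for gained sites, the largest mixed split, lost sites and sites acetylated in both control libraries, with all deposited peaks and at equal list length. Black lines give the share after moving the H3K27ac sites by 20 kb; gained bars stand at 49.6%, 68.0% and 34.2% with all peaks and at 60.0%, 69.1% and 40.1% at equal list length.

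Wild-type p63 plus KLF4 was also set directly against the other p63 vectors, a comparison chosen after the data were seen. At equal list length, 3507 sites were acetylated in both of its libraries and in neither of wild-type p63, and 6706 the other way, with mixed splits of up to 1815. Of the former, 54.9% held a p63 site of wild-type p63 plus KLF4, 18.9% of wild-type p63 and 50.8% a KLF4 site. Of the latter, 21.0% and 44.5% held these p63 sites and 2.43% a KLF4 site. Of the sites in the largest mixed split, 34.3% held a p63 site of wild-type p63 plus KLF4. Against the mutant, 1744 sites were acetylated only with wild-type p63 plus KLF4 and 2416 only with the mutant, both below the mixed split of 2934. A p63 site of wild-type p63 plus KLF4 lay in 76.8% of the former, in 9.73% of the latter and in 34.0% of the mixed sites. A p63 site of the mutant lay in 50.1% of the former and 9.89% of the latter. With all peaks, mixed splits of 18079 and 20528 sites exceeded the real counts in both comparisons.

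Some sites were gained with more than 1 vector. Wild-type p63 plus KLF4 and the mutant had 1364 gained sites in common, 12.8 times the 106.4 given by independent lists. Wild-type p63 shared 1005 with wild-type p63 plus KLF4 (2.92 times) and 887 with the mutant (2.07 times). Simulated unchanged groups with the same controls gave 3.27 times. Their lists averaged 4945.9 gained sites for every pair and gave all libraries the same rates, so they carry neither the real list sizes nor the peak-name classes that the KLF4 vectors share with the controls, and no pair is called above or below chance from them. A split of the controls would leave 1 library on each side and was not made, and part of any overlap may come from the shared controls.

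Sites gained with all 3 p63 vectors numbered 454, and 86.1% of them held a p63 site. The site with the most p63 sites, 5, lay on chromosome 15 from 81131783 to 81145274 and had no peak of any antibody in the control libraries. Wild-type p63 plus KLF4 replicate 1 covered nearly all of it with 1 H3K27ac peak from 81131852 to 81145198. Wild-type p63 alone had Flag peaks only at the right end of the site, from 81144932 to 81145490 and from 81145173 to 81145434 in its replicates. Its H3K27ac peaks were short, with 1 at the right end in replicate 1, from 81145002 to 81145203, and 3 spread over the site in replicate 2. Next in rank were sites on chromosome 9 from 92044088 to 92053336, chromosome 3 from 46983028 to 46991270 and chromosome 11 from 3022036 to 3028388, each with 4 p63 sites.

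**Figure D5:**
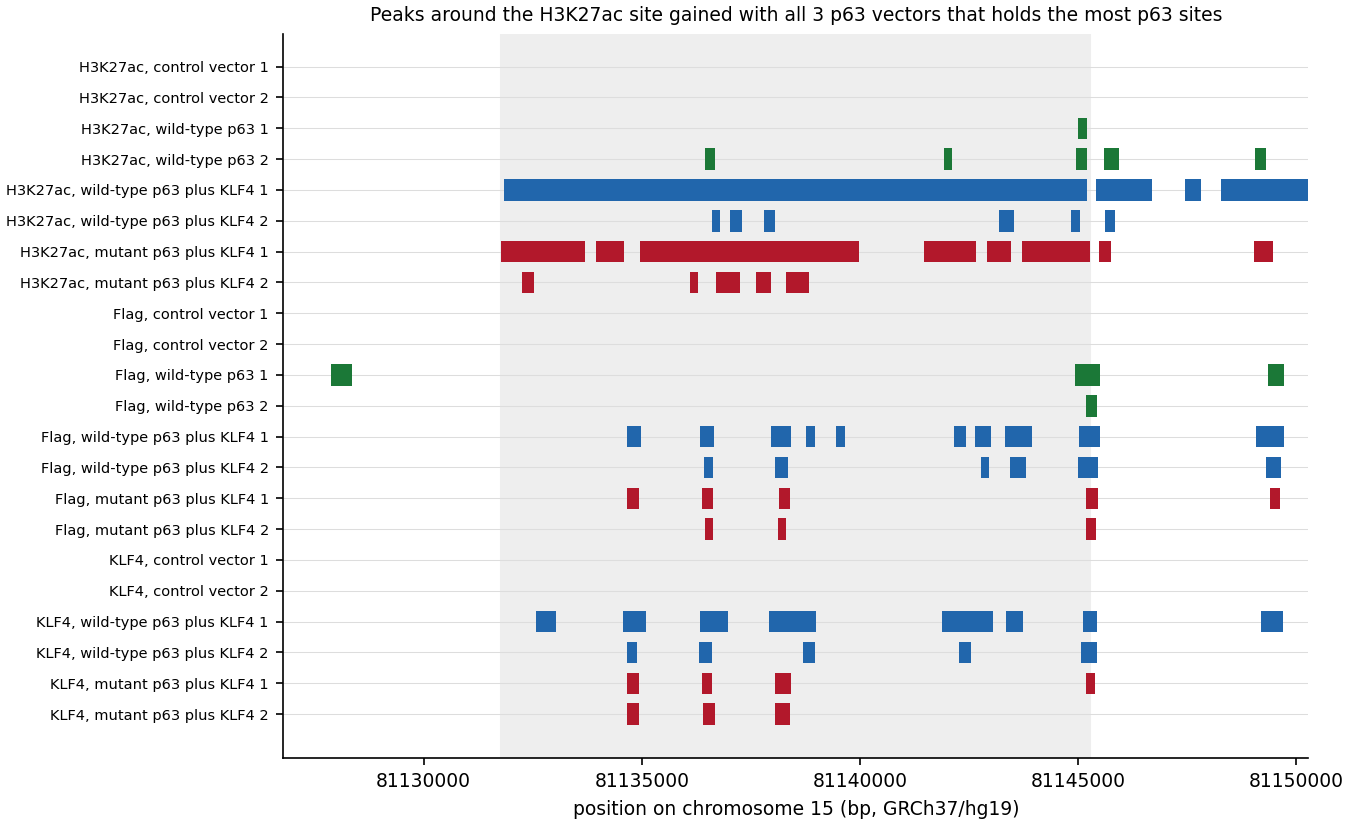
Deposited peaks of each library (bars, to scale) along chromosome 15 in GRCh37/hg19, with the position in bp on the horizontal axis and 1 line per library of each antibody. The shaded span from 81131783 to 81145274 is the gained H3K27ac site; the control libraries have no peak in it, and wild-type p63 alone has Flag peaks only at its right end.

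The last question was whether fibroblast sites lose acetylation with p63, and the direction of the values depended on the control library that defined the sites. Of the 98854 peaks of control replicate 1, the p63 libraries covered 34.8% ± 6.99 (SD, n = 6) and control replicate 2 covered 28.9%; the one-sided exact permutation p was 0.857, in a design with 1 control library that cannot give a p below 0.143 and so decides nothing. The difference of 5.92 points was 22.1 with all deposited peaks. Within the class without prefix, wild-type p63 gave 31.6%, wild-type p63 plus KLF4 23.9% and the mutant 32.4%. Of the 45415 peaks of control replicate 2, control replicate 1 covered 92.5%, and each p63 library covered less: 65.8% and 79.4% with wild-type p63, 71.7% and 51.4% with wild-type p63 plus KLF4, and 83.6% and 72.9% with the mutant. In the class BJ- of that control library, the values were 71.7% and 83.6%. With all deposited peaks control replicate 1 covered 97.59%, and each p63 library still covered less. The shares were then 82.25% and 94.99% with wild-type p63, 90.2% and 51.4% with wild-type p63 plus KLF4, and 95.16% and 84.81% with the mutant. All but wild-type p63 plus KLF4 replicate 2 thus lay nearer to control replicate 1 than at equal list length. The size of the deficit therefore depended on the peaks used. The sites of control replicate 2 were counted after the data were seen and not tested. H3K27ac libraries did not group by vector in bases shared. The mean Jaccard index at equal list length was 0.366 for replicates and 0.381 for other pairs, one-sided exact p = 0.667 over 105 pairings. Measured as the share of peaks that overlap, the order turned, with replicates 0.118 higher and an exact p of 0.0095, the smallest possible. Pairs of different vectors had a mean Jaccard index of 0.443 within a peak-name class and 0.344 between classes. The replicates of a vector, all of different classes, lay between these values. Likeness within a class would lower the replicates in the test over pairings. It may therefore hide a grouping by vector in bases shared, but would not by itself give the higher share of overlapping peaks. List length, which goes with class here, was not tested as a source of either result.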

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

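The test of equal-number ranking was chosen after the result was seen, as were the classes of sites.

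At sites bound only with wild-type p63, a set of 10479 chosen for lacking Flag peaks with the KLF4 vectors, acetylation lay above both controls with wild-type p63 and below the control of the same peak-name class with wild-type p63 plus KLF4. Wild-type p63 libraries reached 18.6% and 26.6%, above both controls (12.2% and 6.79%). Wild-type p63 plus KLF4 libraries reached 8.09% and 4.03%, and differed from the control of their peak-name class by −4.06 and −2.77 points. The means of these vectors differed by −16.56 percentage points, and the difference between their effects was not tested. The mutant libraries differed from their class control by −2.82 and −0.63 points. Over all 41658 wild-type p63 sites no decrease was seen: wild-type p63 plus KLF4 lay 7.58 and 2.40 points above its class controls and the mutant 1.83 and 4.04 points.

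Why KLF4-vector libraries lie below their class controls at these sites remains open, and part of it may follow from the choice of sites, which requires that no Flag peak was called in those same cells. Ranking at equal list length may push weak sites out when new strong peaks enter. With all deposited peaks, 3 of the 4 KLF4-vector libraries stayed below their class control and 1 did not. Both libraries of wild-type p63 plus KLF4 stayed below, at 16.6% against 20.0% and 4.03% against 7.16%. The mutant gave 16.0% against 20.0% in replicate 1 and 8.46% against 7.16% in replicate 2. List lengths differ here, so over the 4 libraries equal-number ranking cannot be told apart from a real decrease. A general loss of control H3K27ac sites would leave sites acetylated in both controls with the same chance of being kept with or without p63. They were kept more often at p63-only sites than at sites without p63, by a median of 10.3 points, which is neither that equality nor the deficit that a loss aimed at p63-only sites would give. A biological explanation, that KLF4 draws p63 or acetylation away from these sites, was not tested.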

How the results depend on the processing

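Alternatives chosen after seeing the data were the crossed and peak-name blocks, all peaks for fibroblast sites, equal list length and equal p63 site number for bound gained sites, leaving out a replicate for KLF4 at p63 sites and for bound gained sites, and all those for new acetylation and for the KLF4 contrast. Over 29 results, 127 alternatives were run: 78 kept direction and side of the threshold or stayed within a tolerance, 40 moved further, 8 no longer passed 0.05 and 1 reversed. The tolerance was 1.5 times for a count and, for a share, the SD between the values of the 2 single replicates. That SD ran from 2.19 to 26.01 points, so a wide one hides large moves: for gained sites with p63 it was 17.4 (wild-type p63), 15.3 (with KLF4) and 5.87 (mutant). The cause was not tested unless the construction shows it.

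The more significant 50% of peaks gave 21426, 24812 and 14379 p63 sites (wild-type p63, wild-type p63 plus KLF4, mutant) and 10590 and 15151 KLF4 sites, fewer by construction, and lowered the mutant p63 sites with KLF4 to 26.6%. Leaving out a replicate gave 44051 to 148254, 53567 to 119518 and 32772 to 58386 p63 sites and 24285 to 115076 and 42459 to 50177 KLF4 sites. Equal list length gave 6569 gained and 3496 lost sites for wild-type p63, 4698 lost with wild-type p63 plus KLF4 and 2083 lost with the mutant, and 40.1% of gained mutant sites with p63. Leaving out a replicate number, which drops the vector and the control library together, gave 12886 to 103110 gained (the latter without replicate 1) and 1444 to 43423 lost (wild-type p63), 7822 to 45412 and 11423 to 34438 (with KLF4), and 16325 to 22653 and 3452 to 27161 (mutant). Equal numbers of p63 sites moved the sharing between wild-type p63 plus KLF4 and the mutant to 55.7% and 56.3% and gained sites with p63, for wild-type p63 plus KLF4, to 47.7%. Leaving out a replicate moved the sharing of wild-type p63 plus KLF4 with wild-type p63 to 42.0% to 54.5%. It gave 25.3% to 58.3% and 37.4% to 46.3% of p63 sites with KLF4 (wild type, mutant), and 22.6% to 47.3%, 32.2% to 53.8% and 17.6% to 25.9% of gained sites with p63. Single replicates of a vector gave 21.3% to 53.6%, 6.03% to 42.8% and 9.71% to 28.6% new acetylation. The H3K27ac grouping reversed to 0.118 when measured as the share of overlapping peaks.

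Replicate differences correlated only between −0.01 and 0.09 across vectors, which gave no sign of pairing. Mixed splits at equal list length did follow the replicate number with the KLF4 vectors. Sites of control 1 and vector 1 alone numbered 2430 with wild-type p63 plus KLF4 and 2638 with the mutant. Sites of control 1 and vector 2 alone numbered 304 and 488. With wild-type p63 the order was crossed, at 405 and 1673. With the KLF4 vectors the numbers also part the peak-name classes and the longer from the shorter lists, so these cannot be told apart from pairing there. With wild-type p63, where the number crosses both, the larger count went with class and list length and not with the number. With the replicate block, the exact p was 0.0625 for H3K27ac at p63 sites (7.84 points), the smallest that block allows, with the real split the most extreme, and 0.167 for KLF4 sites without p63 (8.33 points). A block with the numbers of wild-type p63 crossed, added after the data were seen although the correlations did not call for it, also gave 0.0625 and 0.167. For the KLF4 contrast (15.02 and 13.78 points) both the replicate block and the peak-name block gave an exact p of 0.0556, the smallest these blocks allow, with the real split the most extreme; single replicates gave 11.39 to 18.65 and 11.52 to 16.04 points with p = 0.333, the smallest exact value of 2 against 2 libraries. Not run were the 50% overlap for gained and lost sites, which changes nothing because peaks lie inside union sites, and the gene-list and motif alternatives. Depth is unknown, so sites missing from short lists cannot be read as absent.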

Other observations

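The tests of library depth and of the peak-name class below were chosen after the result was seen, as were the values on shared sites, KLF4 sites and control Flag peaks.

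At p63 sites bound with all 3 p63 vectors, H3K27ac was frequent already in control cells. At equal list length it covered 32.9% ± 9.11 (SD, n = 2) of these sites with the control vector, 51.5% ± 6.34 (SD, n = 2) with wild-type p63, 49.1% ± 17.2 (SD, n = 2) with wild-type p63 plus KLF4 and 43.5% ± 7.49 (SD, n = 2) with the mutant. Each of the 5 libraries with a control of its peak-name class lay above that control, by 9.41 to 21.9 points. KLF4 sites were also often acetylated in control cells, at 44.2% and 26.8% in the control libraries for the sites of wild-type p63 plus KLF4, and at 52.4% and 32.7% for those of the mutant. None of these differences was tested.

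The control Flag libraries differed widely, with 29710 and 948 peaks for an empty vector. Of the 29710 peaks, 26.8% overlapped H3K27ac of the control cells, against 7.81% after moving them. They recurred in 45.4% of cases in mutant replicate 1 and 26.9% in wild-type p63 plus KLF4 replicate 1, which share the peak-name prefix BJ-. In the other p63 libraries they recurred in 10%, 5.33%, 4.76% and 5.90% of cases.

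H3K27ac sites gained with wild-type p63 were weighed against technical sources. Library depth alone would make them like the sites of the mixed splits, but they held a p63 site 5.54 times as often as the largest mixed split with all peaks, and in 60.0% against 22.2% of sites at equal list length. With all peaks that split holds only sites of the longer list of each vector, a low comparator. Sites acetylated in both controls held a p63 site in 26.8% of cases with all peaks and 27.6% at equal list length. A part played by depth is therefore not excluded. Unequal peak numbers alone would leave no more gained than mixed sites at equal list length, and 3.93 times as many were found. That largest mixed split also parts the 2 libraries without prefix from the other 2, so a processing batch that follows the peak-name class would make gained sites like it too, yet they held a p63 site 2.7 times as often at equal list length, and within the class wild-type p63 replicate 1 lay 16.1 points above the control at wild-type p63 sites. This argues against such a batch as the cause of the whole pattern; its part in replicate 2, which has no control of its class, a difference in handling that peak names do not mark, and a response to p63 stay open.

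The higher control acetylation of mutant p63 sites was weighed in the same way. If only the strongest sites had been called with the mutant, the strongest wild-type p63 plus KLF4 sites in equal number would reach its share, yet the mutant stayed 11.4 points above them. Mutant sites that are also wild-type sites lay 11.7 points above all wild-type p63 plus KLF4 sites. This was meant to test unspecific Flag signal at open chromatin in the mutant libraries, but such signal would itself pick out the acetylated wild-type sites, so it stays open. A lower amount of mutant protein, which was not analysed here, and a preference of mutant p63 for acetylated chromatin stay open as well.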
